A study of Mus musculus with 12 samples.

How the data were processed

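RNA of the diaphragm of 12 mice was sequenced after TruSeq library preparation, from 4 groups of 3: NSG and FKRPP448L-NSG mice that did not swim, and mice of both genotypes that swam 1 h per day for 2 weeks. Per the submitters' processing notes, the authors aligned reads to mm10 with TopHat2 2.0.9 and pooled, scaled and tested them with Cuffdiff 2.2.1. The 4 deposited tables hold, at gene and at transcript level, a tracking table and a table of pairwise tests, for 23284 gene entries and 30073 transcripts. Per the file headers, the values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 value per group and a lower and upper confidence bound. Fold changes are given by the authors as log2 of the ratio of the group FPKM values. The test statistic is a score of the authors' Cuffdiff run. The p-value and the q value were likewise deposited by the authors. The group columns name the control strain WT, which was taken as NSG because the labels give no other control. The tables hold no counts, so the depth per library and the counting error were unknown, and precision was read from the authors' intervals alone.

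The deposited tests cover 6 pairs of groups. The 4 pairs that differ in 1 factor were used, the genotype difference without and with swimming and the swimming difference in each genotype, and the 2 pairs that differ in both factors were left out. A gene was called when the authors' q value was 0.05 or less and the test status was OK. The q values were checked to be a Benjamini-Hochberg adjustment over all 81081 tests with that status. The smallest deposited p-value was 5e-05, shared by 3.43% of tests, so genes were ranked by fold change and not by p. Called genes listed at 0 in 1 group have no fold and were counted without one: 28 and 10 in the genotype comparisons without and with swimming, and 8 and 13 in the swimming comparisons of FKRPP448L-NSG and NSG mice. Cuffdiff had skipped 8 genes with too many fragments in some group, such as Alb of liver and Acta1 of muscle, and their 0 values were not used. FPKM values were read from the tracking table and fold changes from the test table. The ratio of the former differed from the latter by more than 0.01 on the log2 scale for 13 genes, 0 of them called by Cuffdiff. Gene positions came from GENCODE M21 on mm10.

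Before the data were examined, 30 gene lists for muscle, immune and other cell types and pathways were fixed, and so were the comparisons, the tests and a rule for naming genes. The rule named, for each comparison, the 10 called genes with the highest and the 10 with the lowest log2 fold change, among those with 1 FPKM or more in a group and above 0 in both and without a predicted or clone name. It added up to 4 called members of each list with 3 or more called, and always Fkrp, Dag1, Large and the sex-linked genes. Other list members, the genes that moved with swimming in both genotypes and the genes higher or lower in both states were named after their values were seen. For each list the number of measured genes (status OK), of higher and lower calls, and the number called after Benjamini-Hochberg adjustment over the list alone were counted. The median log2 fold change of members at 1 FPKM or more was placed among 10000 random lists of genes of the same expression, drawn from 20 bins. An enrichment of called genes in a list was tested with Fisher's exact test, one-sided, and adjusted over 120 list by comparison tests, of which 18 passed 0.05. A further 9 lists (further liver genes, lung, simple epithelium, Kupffer cell, peritoneal macrophage, MHC class II, fasting liver, imprinted genes and p53 targets) were written after the data had been seen. Genes are not independent of each other, so overlap and enrichment tests over genes describe the lists and do not stand for mice.

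The difference between the swimming effects of the genotypes, which was not among the deposited tests, was tested per gene with an approximate two-sided z test. The difference of both log2 fold changes was divided by the root of the summed variances of the 4 log2 FPKM values, each variance taken from the upper confidence bound as 2 standard deviations by the delta method. Genes with status OK in the 4 groups, above 0 in all and at 1 FPKM or more in 1 were tested, with Benjamini-Hochberg adjustment at 0.05. The deposited score was within 1% of the log fold change over the same interval-based deviation in 99.9% of tests. The deposited p-values of the authors corresponded to a z 1.75 times larger (5th to 95th percentile 1.57 to 1.82), close to the root of 3 (1.73). The z test is therefore stricter than the deposited tests, and a version with the variance divided by 3 was added after seeing this. On data simulated from the deposited values (12737 genes), the z test recovered 0 of 100 differences of log2 1 and 7 of 100 of log2 3, with 0 unchanged genes called. With the variance divided by 3 it recovered 4 and 91, with 4 unchanged genes called. The simulation averaged 3 values per group, each drawn with the full interval spread, so it took the variance divided by 3 as true. It therefore cannot tell which variance fits the mice. Of 200 random lists 6.50% lay outside the central 95%, and all 50 lists shifted by log2 1 lay above it.

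Genes were said to follow the liver list when the Pearson correlation of their 4 log2(FPKM + 1) group values with the mean over that list, without Alb, was 0.9 or more. It served only to mark genes for counting and filtering, since 4 values are too few for a correlation to be reported. The filter reads the same group values as the comparisons, so a gene's own change decides whether it is removed, and liver genes of another pattern, such as Aldob and Bhmt, stay in. Overlap of called genes between comparisons was tested with Fisher's exact test among genes tested in both, with the overlap of independent lists as n1 x n2 / N. It was one-sided, for more shared genes than by chance, and a two-sided p was added later for directions that disagree between the states. Called genes within 20 Mb of Fkrp were compared with all other tested genes by Fisher's exact test, two-sided. Alternatives fixed beforehand were adjustment within a comparison, a q of 0.01, a minimum of 1 FPKM, a minimum absolute log2 fold change of 1, transcript-level tests, intervals that do not overlap, centring on the median, a pseudocount of 1 FPKM, other FPKM minimums and variances for the z test, and other windows around Fkrp. Leaving out mice, a block by replicate number and regrouping of samples were not possible with 1 value per group. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.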

Results

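RNA of the diaphragm, the main muscle of breathing, was sequenced from 12 mice aged 8 to 10 weeks, in 4 groups of 3 mice each. NSG mice are an immunodeficient strain without mature T cells, B cells or natural killer cells. FKRPP448L-NSG mice carry a mutation of Fkrp on that background. Fkrp encodes fukutin-related protein, an enzyme that adds sugar phosphates to alpha-dystroglycan, the receptor that ties muscle fibres to their basement membrane, and mutations of it cause muscular dystrophy. Mice of each genotype either swam for 1 h per day over 2 weeks or did not swim. The mouse numbers in the sample titles form separate ranges for swum and not swum FKRPP448L-NSG mice, and another, unbroken range for NSG mice. What these ranges stand for is not stated. A difference between these sets of animals cannot be told apart from genotype, or from swimming in FKRPP448L-NSG mice. The deposited tables held 1 pooled FPKM value per gene and group, with a confidence interval from the authors' Cuffdiff run, and no value per mouse. Read depth per library was therefore unknown, no spread between mice was computed, and intervals in brackets after an FPKM value are the authors' own. Over all genes, the median width of that interval to either side of the value lay between 61.0% (swum FKRPP448L-NSG) and 63.7% (NSG not swum) of the value. Genes at 1 FPKM or more numbered 12246 in NSG mice that did not swim, 12479 in swum NSG mice, 12375 in FKRPP448L-NSG mice that did not swim and 12218 in swum FKRPP448L-NSG mice.

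The mutated gene itself was read at similar levels in the 4 groups. Fkrp (mm10 chromosome 7, 16809246 to 16816732, minus strand) stood at 17.2 FPKM (4.86 to 29.5) in NSG and 18.3 FPKM (4.19 to 32.4) in FKRPP448L-NSG mice that did not swim, and at 15.4 FPKM (3.66 to 27.2) and 20.5 FPKM (5.31 to 35.7) in swum mice, and was not called in any comparison of the authors' deposited table. A substitution of 1 amino acid need not alter the amount of messenger RNA, so these values do not check the genotype labels. Dag1, which encodes dystroglycan (mm10 chromosome 9, 108204634 to 108263958, minus strand), was higher in swum FKRPP448L-NSG than in swum NSG mice at 69.4 FPKM (23.4 to 115) against 32.2 FPKM (12.9 to 51.6), a log2 fold change of 1.11 (q = 0.0300 in the authors' deposited table). Without swimming the difference of Dag1 was 0.96 (q = 0.138 in the authors' deposited table), not called. Large, whose enzyme extends the sugar chain of alpha-dystroglycan, differed by 0.06 without and 0.08 with swimming and was not called. Among the 16 measured genes of dystroglycan glycosylation, 0 were called by Cuffdiff without swimming (1 at an unadjusted p under 0.05; 0 adjusted over the list alone) and 1, Dag1, with swimming (1 adjusted over the list alone), in the authors' deposited table.

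The first comparison asked how the diaphragm of FKRPP448L-NSG mice differed from that of NSG mice without swimming. Genes of newly formed muscle fibres were among the higher genes. Embryonic myosin heavy chain Myh3 (mm10 chromosome 11, 67078300 to 67102291, plus strand) was at 44.0 FPKM (0 to 91.0) in FKRPP448L-NSG against 0.645 FPKM (0.105 to 1.18) in NSG mice, a log2 fold change of 6.09. Myl4, a myosin light chain of embryonic muscle (mm10 chromosome 11, 104550663 to 104595753, plus strand), was higher by 5.49, Actc1, the actin of heart and fetal muscle, by 4.12, and Tmem8c, or myomaker, which fuses myoblasts into fibres, by 7.02. In the authors' deposited table, 11 of the 20 measured genes of the myogenic regeneration list were higher, 0 were lower and 9 were not called (12 adjusted over the list alone). The median log2 fold change of that list was 2.06, at percentile 100 of 10000 random lists of the same size and expression.

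Genes that muscle fibres use at the nerve contact or switch on when innervation is lost were higher as well. Chrng, the fetal gamma subunit of the acetylcholine receptor (mm10 chromosome 1, 87204657 to 87212694, plus strand), was at 8.96 FPKM (1.71 to 16.2) against 0.252 FPKM (0 to 0.588) (log2 5.15), and Ncam1, Musk and Runx1 were higher by 2.46, 2.26 and 2.25. Of the 12 measured genes of the list for denervation and neuromuscular junction, 7 were higher and 0 lower in the authors' deposited table (8 adjusted over the list alone; median log2 1.54). The fibrosis list had 11 higher and 0 lower genes of 30 in the authors' deposited table (17 adjusted over the list alone; median log2 1.18). Its leading members were Postn, or periostin (mm10 chromosome 3, 54361109 to 54391037, plus strand), at 287 FPKM (0 to 713) against 16.1 FPKM (6.57 to 25.6) (log2 4.16), tenascin C (Tnc, 3.95), Col5a1 (2.08) and the collagen cross-linker Lox (1.98). Of 14 basement membrane and integrin genes, 2 were higher in the authors' deposited table (6 adjusted over the list alone).

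Macrophage transcripts were higher in the diaphragm samples of FKRPP448L-NSG mice, which also held more lung transcripts. Whether the macrophage transcripts came from muscle or from lung was not tested. Gpnmb, a glycoprotein of phagocytic macrophages (mm10 chromosome 6, 49036546 to 49070929, plus strand), was at 15.0 FPKM (5.81 to 24.3) against 0.550 FPKM (0.0308 to 1.07) (log2 4.77), and Ms4a7, Itgax and the monocyte chemokine receptor Ccr2 were higher by 3.90, 3.72 and 2.53. Of 25 macrophage and monocyte genes, 16 were higher and 0 lower in the authors' deposited table (23 adjusted over the list alone; median log2 1.56). The chemokine and cytokine list had 6 higher genes and 1 lower gene of 15 in the authors' deposited table (9 adjusted over the list alone), with Ccl8 at 3.93, Ccl7 at 2.54, Ccl2 at 2.00 and Il1b at 1.96. Of 6 measured neutrophil genes, 3 were higher in the authors' deposited table (5 adjusted over the list alone): S100a8 by 3.32, S100a9 by 2.27 and Lcn2 by 1.52. Only 2 of 13 lymphocyte genes had enough signal for the authors' test, and 1 of them, Cd4, was higher at 0.842 FPKM (0.0697 to 1.61) against 0.111 (1 adjusted over the list alone in the authors' deposited table). Of 19 cell cycle genes, 3 were higher in the authors' deposited table (7 adjusted over the list alone), namely Mki67, Top2a (2.45) and Tpx2 (2.21), with Mki67 at 0.767 FPKM (0.177 to 1.36) against 0.167 FPKM (0.00944 to 0.325). Cdkn1a, the cell cycle inhibitor p21, was higher by 2.65 and led the 3 higher genes of 14 in the atrophy and proteolysis list of the authors' deposited table (5 adjusted over the list alone), with Eda2r at 1.69 and Foxo3 at 1.54.

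Transcripts that respond to glucocorticoid hormones formed another higher group without swimming. Ddit4 (mm10 chromosome 10, 59949669 to 59951834, minus strand) was at 102 FPKM (0 to 244) in FKRPP448L-NSG against 4.79 FPKM (1.49 to 8.08) in NSG mice (log2 4.41), and the metallothioneins Mt2 and Mt1 and the clock gene Per1 were higher by 3.38, 2.55 and 2.92. Of the 11 measured genes of this list 7 were higher and 0 lower in the authors' deposited table (11 adjusted over the list alone; median log2 1.68). The interval of Ddit4 reached down to 0 in this group. The same group was the only group with Xist, the transcript of the inactive X chromosome of females, above 0.1 FPKM: 6.01 FPKM (0 to 12.9), against 0.00364 in NSG mice that did not swim, 0.0170 in swum NSG and 0.00822 in swum FKRPP448L-NSG mice. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in the 4 groups and called in no comparison of the authors' deposited table, in which Xist was the 1 called gene of the 5 sex-linked genes, with swimming in FKRPP448L-NSG mice (1 adjusted over the list alone). Ddx3y, for example, stood at 27.4, 31.5, 28.6 and 26.5 FPKM in the same order of groups as Xist. In the circadian clock list 3 of 15 genes were higher in the authors' deposited table (3 adjusted over the list alone): Per1, Per2 (2.31) and Cry2 (1.54). Among 18 immediate early and heat shock genes 4 were lower in the authors' deposited table (5 adjusted over the list alone), with Nr4a1 at -2.26, Egr1 at -1.96, Fos at -1.26 and Ier2 at -1.01.

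Transcripts of other tissues differed between these groups too. Mesothelium, the cell layer that covers the diaphragm, had 4 lower genes of 8 in the authors' deposited table (7 adjusted over the list alone): Krt19 (-2.60), Upk3b (-1.16), Krt8 (-1.13) and Krt18 (-1.12). Alongside these, NSG mice that did not swim carried transcripts of glandular and intestinal epithelium that the other groups nearly lacked. Dmbt1, a mucosal glycoprotein (mm10 chromosome 7, 131032053 to 131121630, plus strand), was at 172 FPKM (0 to 364) there and at 0.0116, 0.0138 and 0.0929 in swum NSG, not swum FKRPP448L-NSG and swum FKRPP448L-NSG mice. The pancreatic protease Ctrb1 was at 35.5 against 0.311 FPKM (log2 -6.83), and Anxa13, Slc26a3 and the epithelial mucin Muc1 were lower in FKRPP448L-NSG mice at -6.51, -5.26 and -4.12. Lung transcripts were found in FKRPP448L-NSG mice, with the surfactant gene Sftpb at 12.7 against 0.103 FPKM (log2 6.95) and the alveolar gene Ager at 10.9 against 0.265 (log2 5.36), beside the higher macrophage genes. The complement list had 1 higher gene of 11, the receptor C3ar1 (1.75), and the interferon list 2 of 18, Mx1 (3.50) and Rsad2 (1.29), in the authors' deposited table (1 and 6 adjusted over the list alone). The erythroid list had 0 of 5 called by Cuffdiff in the authors' deposited table (1 at an unadjusted p under 0.05; 0 adjusted over the list alone). The 9 liver genes had a median of 0.00, with 0 called by Cuffdiff in the authors' deposited table and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone).

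The contractile and metabolic genes of the fibres were not called between the genotypes without swimming. Among 10 slow fibre, 14 fast fibre, 20 mitochondrial, 15 glycolysis and 18 fatty acid oxidation genes, Cuffdiff called 0 in the authors' deposited table, over all genes and adjusted over the list alone, and 2, 0, 0, 0 and 3 had an unadjusted p under 0.05. Slow myosin Myh7 was at 134 FPKM (24.4 to 244) against 156 FPKM (18.4 to 294). Of the 14 dystrophin complex genes 1 was higher in the authors' deposited table (1 adjusted over the list alone), and dystrophin itself (Dmd) had a difference of 0.43 and utrophin (Utrn) of 0.54, neither called. Of 11 endothelial genes 0 were called by Cuffdiff in the authors' deposited table (1 at an unadjusted p under 0.05; 0 adjusted over the list alone), and of 7 Schwann cell genes 2 were lower (3 adjusted over the list alone), the myelin gene Mpz at -1.37 among them. The adipocyte list had 1 higher gene and 1 lower gene of 15 in the authors' deposited table (2 adjusted over the list alone): Ucp1 of brown fat, listed at 0 in NSG mice and thus without a fold, and Adipoq (-1.23). The unfolded protein response list had 0 of 14 called by Cuffdiff in the authors' deposited table (1 at an unadjusted p under 0.05; 0 adjusted over the list alone). In all, 684 of 13557 tested genes were called between the genotypes without swimming in the authors' deposited table, 443 higher and 241 lower in FKRPP448L-NSG mice. Intervals that do not overlap were found for 99 genes, 49.5% of them higher, so the excess of higher genes was not seen by that criterion. With 1 pooled value per group, it could not be seen how many of the mice showed any of these differences.

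**Figure D1:**
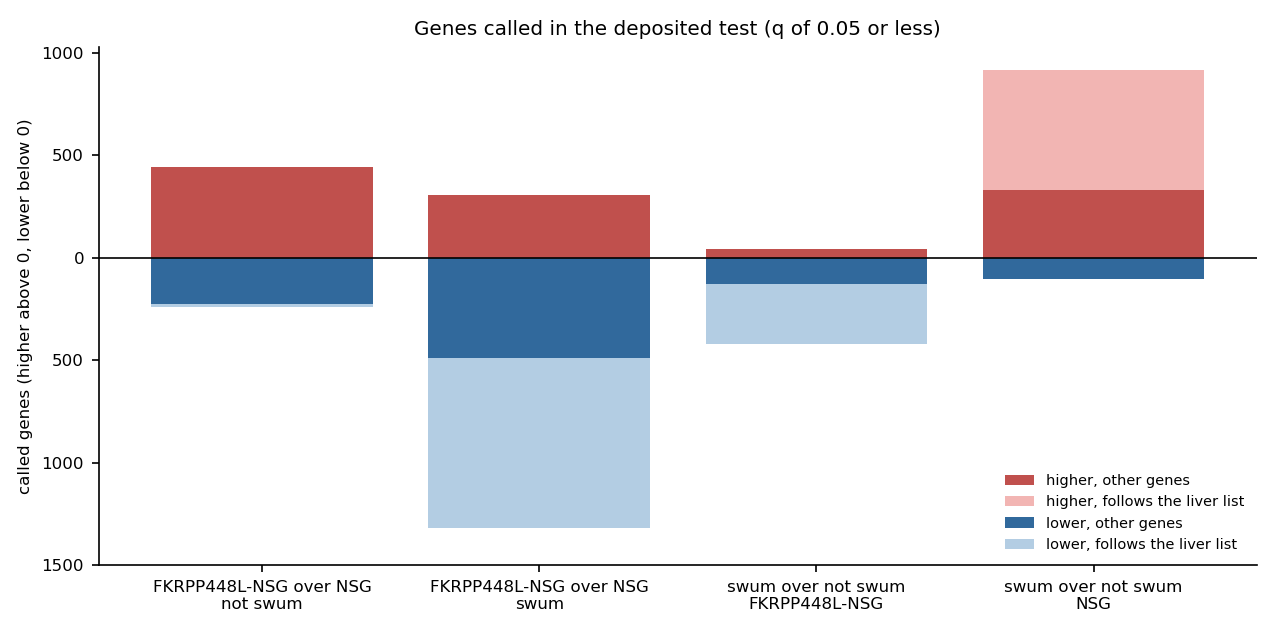
Number of genes called at a q of 0.05 or less in the authors' deposited table, for each of the 4 comparisons on the horizontal axis, with higher genes above and lower genes below 0. Pale parts are genes whose 4 group values follow the liver list, which make up 830 of the 1319 lower genes of swum FKRPP448L-NSG mice and 584 of the 916 genes higher after swimming in NSG mice. Of all tested genes, 11.3% and 11.4% followed it in these comparisons. Following is judged on the same group values.

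The second comparison repeated the genotype contrast in mice that had swum. Muscle regeneration, fibrosis and macrophage genes were again higher in FKRPP448L-NSG mice. Gpnmb was at 35.7 FPKM (7.35 to 64.1) against 0.616 FPKM (0 to 1.25) (log2 5.86), Chrng was higher by 5.21, Myl4 by 5.16, Actc1 by 4.69, Myh3 by 3.51 and the macrophage elastase Mmp12 by 5.54. In the authors' deposited table, 12 of 20 regeneration genes were higher (14 adjusted over the list alone; median log2 2.39), as were 8 of 12 denervation and junction genes (8 adjusted over the list alone; median log2 1.58) and 9 of 30 fibrosis genes (15 adjusted over the list alone; median log2 0.86), with 0 lower in each. Leading fibrosis genes were Tnc (3.30), osteopontin (Spp1, 2.48) and Postn (1.80). Of 25 macrophage genes 9 were higher in the authors' deposited table (12 adjusted over the list alone; median log2 0.81), with Itgax at 4.46, Ms4a7 at 3.21 and Lgals3 at 2.31. The neutrophil list was not higher here, with a median log2 of -1.33 (percentile 0.210) and 0 of 9 genes called by Cuffdiff in the authors' deposited table (3 at an unadjusted p under 0.05; 3 adjusted over the list alone). The chemokines Ccl7 (4.53), Ccl2 (4.22; mm10 chromosome 11, 82035571 to 82037453, plus strand) and Ccl6 (1.62) were the 3 higher genes of 18 in that list of the authors' deposited table (4 adjusted over the list alone). Among 19 cell cycle genes 4 were higher in the authors' deposited table (9 adjusted over the list alone), with Top2a at 2.04. Lung genes stood beside these groups, with the surfactant gene Sftpc at 81.0 against 1.56 FPKM (log2 5.70; mm10 chromosome 14, 70520949 to 70524081, minus strand). Which tissue carried the macrophage genes was not tested here either.

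Of the genes lower in swum FKRPP448L-NSG mice, 62.9% followed the liver list over the 4 groups, against 11.3% of all tested genes. Following is judged on the same group values. The liver list was itself highest in swum NSG and lowest in swum FKRPP448L-NSG mice. Genes lower in this comparison are therefore favoured, and the share is a description only. Ttr, the liver's transthyretin (mm10 chromosome 18, 20665280 to 20674321, plus strand), was at 80.5 FPKM (0 to 172) against 3152 FPKM (0 to 7544) in swum NSG mice, a log2 fold change of -5.29, and the apolipoproteins Apoa2 and Apoa1 and the fetuin Ahsg were lower at -5.28, -4.91 and -4.88. All 8 liver genes that could be tested were lower in the authors' deposited table (8 adjusted over the list alone; median log2 -4.85). The lowest genes, such as Serpina7 (-7.10), Mug2 (-6.66), Apcs (-6.47) and the bile cholesterol transporters Abcg5 (-6.06) and Abcg8 (-5.95), are also known from liver. Complement genes, most of them made by the liver, moved with this list: 8 of 11 were lower and 2 higher in the authors' deposited table (10 adjusted over the list alone), with Cfb at -3.25 and C3 at -2.29. In the interferon list 4 of 18 genes were lower in the authors' deposited table (6 adjusted over the list alone), with Iigp1 at -3.77, and in the circadian list 3 of 15 were lower (3 adjusted over the list alone), with Hlf at -1.76, beside the liver genes. Calls in these lists were not enriched at 0.05 after adjustment (Fisher's exact test, one-sided, adjusted p = 0.477 and 0.673). Of 8 mesothelial genes 6 were lower in the authors' deposited table (8 adjusted over the list alone), with Krt8 at -3.67 and Krt18 at -3.23. Both keratins also followed the liver list over the 4 groups. The erythroid gene Alas2, lower at -3.45, was the 1 called gene of 6 in its list of the authors' deposited table (2 adjusted over the list alone).

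Genes of the glucocorticoid and contractile lists were not called between swum mice of the 2 genotypes. The glucocorticoid list had 0 of 11 genes called by Cuffdiff in the authors' deposited table (1 at an unadjusted p under 0.05; 0 adjusted over the list alone), with Ddit4 at 6.09 FPKM (2.03 to 10.2) against 5.54 FPKM (1.83 to 9.24). The slow fibre, fast fibre, mitochondrial and glycolysis lists had 0 called genes of 10, 14, 20 and 15 by Cuffdiff in the authors' deposited table, also adjusted over the list alone, and 0 at an unadjusted p under 0.05. Of 18 fatty acid oxidation genes 2, Hmgcs2 (-5.14) and Angptl4 (-1.36), were lower in the authors' deposited table (2 adjusted over the list alone). In the authors' deposited table, 1625 of 13586 tested genes were called, 306 higher and 1319 lower in swum FKRPP448L-NSG mice. Intervals that do not overlap were found for 626 genes, 9.11% of them higher. Without the genes that follow the liver list, 795 calls were left, 306 higher and 489 lower.

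The genotype difference was compared between the states, which share no mouse. Of 632 genes called without swimming and tested in both states, 86.7% had the same sign with swimming, and 69.7% of the 1563 genes called with swimming had the same sign without, against 63.6% of all genes tested in both. In the authors' deposited table, 168 genes were higher in FKRPP448L-NSG mice in both states, where independent lists of 428 and 298 genes would share 9.64, and 89 were lower in both, where 19.5 would be shared. Those higher in both held 8 genes of the regeneration list (Actc1, Ankrd1, Igf2, Mybph, Myh3, Myh8, Myl4 and Myog), 7 of the denervation and junction list (Chrna1, Chrnd, Chrng, Musk, Ncam1, Runx1 and Scn5a), 7 of the fibrosis list (Col12a1, Col5a1, Col6a3, Ltbp2, Mmp2, Postn and Tnc) and 8 of the macrophage list (Ccr2, Cd68, Ctss, Gpnmb, Itgax, Lgals3, Ms4a7 and Ptprc). Myog, the transcription factor of differentiating muscle cells, was higher by 2.17 without and 2.75 with swimming, and Cd68 by 2.32 and 1.76. The 89 lower in both held 4 mesothelial genes (Krt8, Krt18, Krt19 and Upk3b). A further 31 genes were higher without and lower with swimming, where 40.9 would be shared (Fisher's exact test, two-sided, p = 0.112), and 0 the other way round, where 4.60 would be shared (p = 0.0158). Without the genes that follow the liver list, the 31 stood against 16.5 (Fisher's exact test, two-sided, p = 0.000741) and the 0 against 4.82 (p = 0.0164). That filter reads the same group values. It cut the genes lower with swimming from 1265 to 454, but those higher without swimming only from 428 to 427. The drop of the expected overlap to 16.5 thus comes from the filter, and its p-value is no evidence of an excess.

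**Figure D2:**
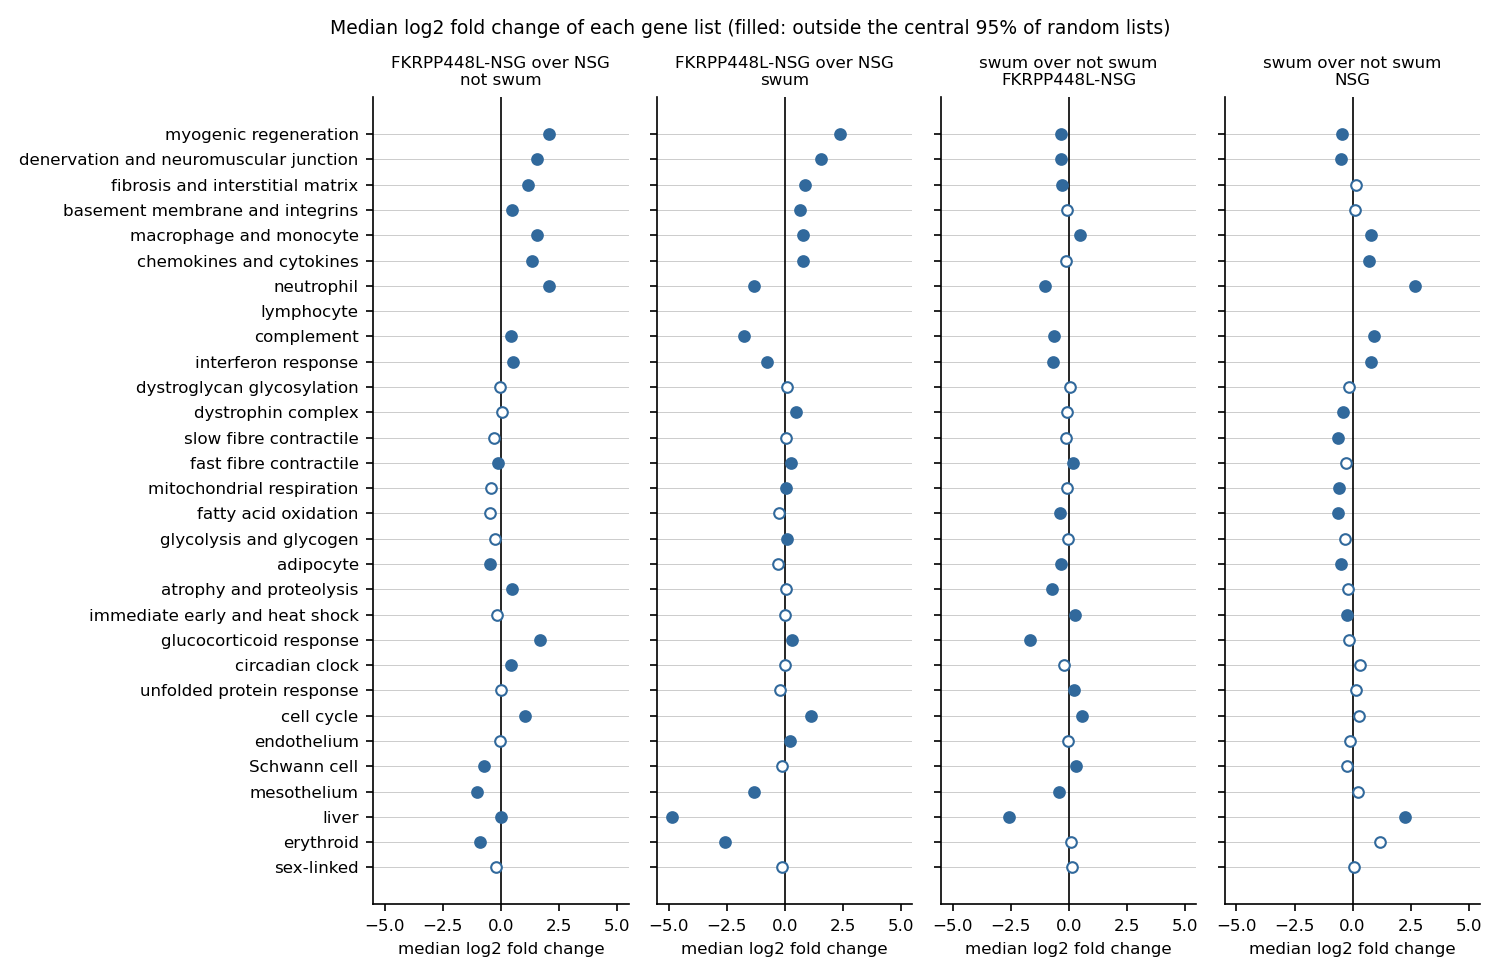
Median log2 fold change (horizontal axis) of the 30 gene lists fixed before the data were examined (vertical axis), 1 panel for each comparison; filled points lie outside the central 95% of 10000 random lists matched on size and expression, open points within it, and the lymphocyte list has no point because too few of its genes reached 1 FPKM. Myogenic regeneration stands at 2.06 and 2.39 in the genotype panels and liver at -2.57 and 2.26 in the swimming panels.

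The third comparison asked what swimming changed in FKRPP448L-NSG mice. Among the 44 genes that rose in the authors' deposited table was Alox15, a lipoxygenase of resident peritoneal macrophages and eosinophils (mm10 chromosome 11, 70344152 to 70352031, minus strand). It went from 5.67 FPKM (1.72 to 9.62) to 44.7 FPKM (18.3 to 71.0) (log2 2.98), and Padi4, Serpinb2, Timd4 and the integrin Itgam rose by 3.39, 3.38, 2.08 and 1.91. The monocyte attractants Ccl2 and Ccl7 rose by 2.40 and 2.39, while Ccl8 fell (-1.42). They were the 3 called genes of 18 in the chemokine list of the authors' deposited table (5 adjusted over the list alone). Of 25 macrophage genes 3 rose and 0 fell in the authors' deposited table (4 adjusted over the list alone): Itgam, Itgax (1.26) and Gpnmb (1.25). The median log2 of the macrophage list was 0.47 (percentile 100), with 7 genes at an unadjusted p under 0.05. Calls in that list were not enriched at 0.05 after adjustment (Fisher's exact test, one-sided, adjusted p = 0.221). Of 8 neutrophil genes 1, Lcn2, fell (-1.63) and 0 rose in the authors' deposited table (1 adjusted over the list alone; median log2 -1.03). Spp1, a matrix protein also made by macrophages, rose from 59.5 FPKM (18.3 to 101) to 172 FPKM (46.0 to 298) (log2 1.53; mm10 chromosome 5, 104435118 to 104441050, plus strand) and was the 1 called gene of 30 in the fibrosis list of the authors' deposited table (1 adjusted over the list alone). The fibrosis list as a whole went the other way, with a median log2 of -0.30 (percentile 0) and 6 genes at an unadjusted p under 0.05. Of 20 regeneration genes 1, Myh3, fell (-1.74, q = 0.0465 in the authors' deposited table, 0 adjusted over the list alone), with a list median of -0.33 (percentile 0.06).

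Glucocorticoid-responsive and liver genes fell with swimming in FKRPP448L-NSG mice. Ddit4 went from 102 FPKM (0 to 244) to 6.09 FPKM (2.03 to 10.2) (log2 -4.07), and Mt2, Mt1 and Per1 fell by 3.61, 3.41 and 2.64 on the log2 scale. Of 11 genes of this list 7 fell and 0 rose in the authors' deposited table (10 adjusted over the list alone; median log2 -1.68). Xist also fell, from 6.01 to 0.00822 FPKM (log2 -9.51, q = 0.0259 in the authors' deposited table). Of 9 liver genes 4 fell in the authors' deposited table (9 adjusted over the list alone; median log2 -2.57), with Apoa2 at -2.77, Ttr at -2.57, fibrinogen beta (Fgb) at -2.57 and Cyp2e1 at -2.30. The genes that fell most included liver enzymes of amino acid and methionine metabolism, Mat1a (-5.41), Bhmt (-5.18) and Tat (-4.77), with Apoa4 at -5.19 and the acute phase gene Saa1 at -5.11. Complement and interferon genes had 2 of 11 and 2 of 18 lower in the authors' deposited table (4 and 3 adjusted over the list alone). Of 17 immediate early genes, Fos rose by 1.08, and Btg2 (-1.84) and Maff (-1.48) fell in the authors' deposited table (5 adjusted over the list alone). The denervation and junction, slow fibre, fast fibre, mitochondrial and glycolysis lists had 0 called genes by Cuffdiff in the authors' deposited table, also adjusted over the list alone, and 1, 0, 0, 1 and 0 genes at an unadjusted p under 0.05. The denervation and junction median was low (-0.31, percentile 0.81) and the fast fibre median high (0.19, percentile 100). The atrophy and proteolysis list had a low median (-0.73, percentile 0). Cuffdiff called 0 of its 14 genes (7 at an unadjusted p under 0.05, 0 adjusted over the list alone). Fatty acid oxidation genes had a low median too (-0.37, percentile 0). Of these 18 genes 2 fell in the authors' deposited table (3 adjusted over the list alone). In the authors' deposited table, 467 of 13354 tested genes were called, 44 higher and 423 lower after swimming. Without the genes that follow the liver list 172 were left, 44 higher and 128 lower. Group intervals that do not overlap were found for 18 genes in this comparison, 9 of them called.

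The fourth comparison asked what swimming changed in NSG mice. Liver genes rose: Cyp2e1, a liver cytochrome, went from 185 FPKM (24.7 to 346) to 1232 FPKM (0 to 2839) (log2 2.73), and Ttr, Ahsg and Serpina1b rose by 2.37, 2.36 and 1.96. Of 8 liver genes that could be tested, 4 rose and 0 fell in the authors' deposited table (8 adjusted over the list alone; median log2 2.26). Cytochromes of liver drug metabolism, such as Cyp2b9 (4.23) and Cyp2c38 (3.98), were among the genes that rose most. Some genes of the complement, interferon and mesothelial lists were called as well, in none of these lists enriched at 0.05 after adjustment (Fisher's exact test, one-sided, adjusted p = 0.194, 0.477 and 0.110). Of 11 complement genes 3 rose in the authors' deposited table (5 adjusted over the list alone), with Cfb at 1.95, and of 18 interferon genes 3 rose (6 adjusted over the list alone), with Iigp1 at 2.18. In the mesothelial list Krt8 (from 45.3 to 128 FPKM) and Krt18 (1.38) rose and Krt19 fell (-1.61) in the authors' deposited table (3 of 8 adjusted over the list alone). Of 6 erythroid genes 2, Alas2 (1.84) and Slc4a1 (2.29), rose in the authors' deposited table (2 adjusted over the list alone).

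Some macrophage and neutrophil genes rose with swimming in NSG mice. Itgam (mm10 chromosome 7, 128062640 to 128118491, plus strand) went from 3.13 FPKM (1.06 to 5.19) to 12.8 FPKM (2.41 to 23.2) (log2 2.03), and Emr1, which encodes the macrophage marker F4/80, Cybb and Cd84 rose by 1.70, 1.64 and 1.58. Of 23 macrophage genes 5 rose and 0 fell in the authors' deposited table (6 adjusted over the list alone). The macrophage median was 0.82 (percentile 100), with 12 genes at an unadjusted p under 0.05. Of 8 neutrophil genes 2, S100a8 (3.66) and S100a9 (2.71), rose in the authors' deposited table (4 adjusted over the list alone). The neutrophil median was 2.71 (percentile 100), with 6 genes at an unadjusted p under 0.05. The liver list rose in the same mice. Neither the macrophage nor the neutrophil list was enriched for calls at 0.05 after adjustment (Fisher's exact test, one-sided, adjusted p = 0.139 and 0.407). In the fibrosis list fibronectin (Fn1) rose by 1.87, while Spp1 (-1.37) and Ctgf (-1.11) fell in the authors' deposited table (3 of 30 adjusted over the list alone). Of genes by which muscle burns fat, Pdk4, which turns fibres from sugar to fat, fell from 562 FPKM (17.7 to 1107) to 158 FPKM (42.2 to 275) (log2 -1.83), and Ucp3 (-1.22) and Acot2 (-1.20) fell, while Hmgcs2, a ketone body enzyme of liver that moved with the liver list, rose (2.37). These were the 4 called genes of 18 in the fatty acid oxidation list of the authors' deposited table (4 adjusted over the list alone; median log2 -0.63), not enriched at 0.05 after adjustment (Fisher's exact test, one-sided, adjusted p = 0.194). The medians of the slow fibre list (-0.63) and of the denervation and junction list (-0.49) were low as well, with 0 genes called by Cuffdiff in the authors' deposited table, also adjusted over the list alone, and 0 and 2 at an unadjusted p under 0.05. The mitochondrial list had a median of -0.57, below most random lists (percentile 0.170), with 0 of 20 genes called by Cuffdiff in the authors' deposited table (1 at an unadjusted p under 0.05; 0 adjusted over the list alone). The regeneration median was low too, at -0.43 (percentile 0.02), as it was with swimming in FKRPP448L-NSG mice. Of its 16 measured genes 1 fell in the authors' deposited table (1 adjusted over the list alone). Of 14 dystrophin complex genes the neuronal nitric oxide synthase Nos1 fell (-1.35) and the syntrophin Sntb1 rose (1.89) in the authors' deposited table (3 adjusted over the list alone). Epithelial genes fell from their level in NSG mice that did not swim, with Muc1 at -4.31, Ctse at -5.51 and Epcam at -4.37. In the authors' deposited table, 1021 of 13458 tested genes were called, 916 higher and 105 lower after swimming, and without the genes that follow the liver list 437 were left, 332 higher and 105 lower. Intervals that do not overlap were found for 87 genes, 59.8% of them higher.

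Swimming was then compared between the genotypes. A set of 14 genes rose in both in the authors' deposited table: Alox15, Atp1a3, Cd5l, Ednrb, Emilin2, Itgam, Itgb2, Msr1, Nfe2, Padi4, Plek, Selplg, Serpinb2 and Timd4. Itgam was the 1 member of the macrophage list among them. Independent lists of 40 and 861 genes would share 2.67 (Fisher's exact test, one-sided, p = 1.42e-07). Gadd45g, Mt1 and Tm4sf4 fell in both, where 2.05 would be shared (Fisher's exact test, one-sided, p = 0.337). Gadd45g fell by 1.94 in FKRPP448L-NSG and by 1.01 in NSG mice on the log2 scale. Of 447 genes called in FKRPP448L-NSG mice and tested in both, 15.2% had the same sign in NSG mice, against 43.3% of all genes tested in both, and 313 genes fell in FKRPP448L-NSG and rose in NSG mice, where 27.2 would be shared. Without the genes that follow the liver list the share with the same sign was 44.7% of 152, against 48.9% of all such genes. Among these, 37 fell in FKRPP448L-NSG and rose in NSG mice, where 2.85 would be shared. Liver genes of another pattern, such as Aldob and Bhmt, pass this filter, so the 37 do not show opposite changes beyond liver. Spp1 was the 1 gene that rose in FKRPP448L-NSG and fell in NSG mice. Its difference between the swimming effects was 2.90, with an approximate z test from the authors' intervals giving q = 0.139, or 2.92e-05 with the variance divided by 3. That test, with Benjamini-Hochberg adjustment, called 298 of 13085 genes, 2 with a higher and 296 with a lower swimming effect in FKRPP448L-NSG than in NSG mice, and 245 of them (82.2%) followed the liver list, which is judged on the same 4 group values. Ddit4 was called with a difference of -4.28 (q = 0.0481). Of the fatty acid oxidation genes called with swimming in NSG mice, Hmgcs2 was called here (-6.05, q = 0.0173). Pdk4 (-0.27), Ucp3 (0.28) and Acot2 (0.00) were not. No gene of the regeneration, denervation and junction, or macrophage list was called by this z test, with 1, 0 and 0 at an unadjusted p under 0.05. On simulated data, which took the variance divided by 3 as true, the test found 7% of differences of 3 on the log2 scale. Under that assumption it misses most differences of that size. With the variance divided by 3, 1 gene of these lists was called, Myh3 of the regeneration list (-2.58, q = 0.00583), and in all the test called 1016 genes.

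**Figure D3:**
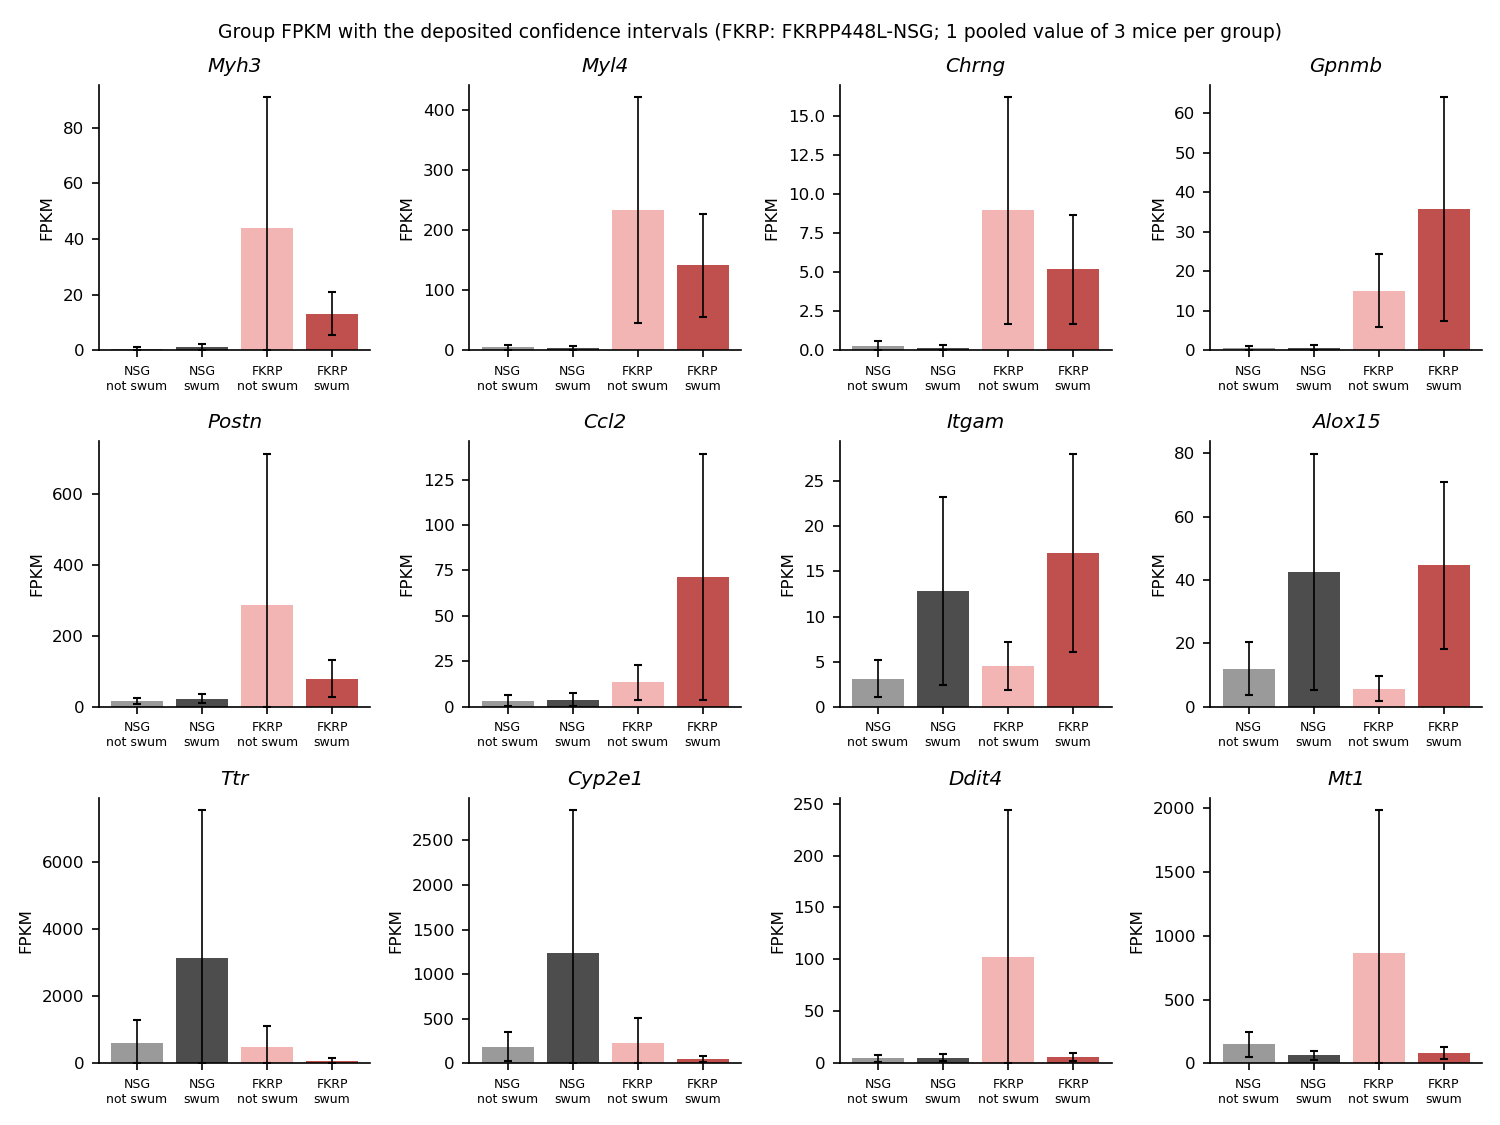
FPKM (vertical axis, from 0) of 12 genes in the 4 groups (horizontal axis); bars are the authors' pooled value of 3 mice and lines the authors' confidence interval. Myh3, Myl4, Chrng, Gpnmb and Postn are higher in both FKRPP448L-NSG groups, Itgam and Alox15 in both swum groups, Ttr and Cyp2e1 highest in swum NSG mice and Ddit4 and Mt1 highest in FKRPP448L-NSG mice that did not swim.

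A mutation moved onto another strain can bring flanking DNA with it, so called genes were counted near Fkrp. Within 20 Mb of Fkrp on chromosome 7, 28 of 350 tested genes (8%) were called between the genotypes without swimming in the authors' deposited table, against 4.97% of the other genes (Fisher's exact test, two-sided, p = 0.0177, 0.0708 after Benjamini-Hochberg adjustment over the 4 comparisons). With swimming 39 of 351 genes near Fkrp and 1586 of 13235 others were called (Fisher's exact test, p = 0.677). The swimming comparisons, in which the genotype is constant, gave 5.20% against 3.45% in FKRPP448L-NSG (Fisher's exact test, p = 0.0998) and 7.27% against 7.59% in NSG mice (p = 0.918). No excess near Fkrp therefore passed the adjusted threshold.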

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

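The comparison of the swimming effects between the genotypes was planned, while every test of an explanation given here was chosen after the result was seen. The z test of that comparison found 298 genes whose swimming effect differed between FKRPP448L-NSG and NSG mice. The 2 positive differences were those of Dmbt1 (16.61), at 172 FPKM in NSG mice that did not swim and 0.0116 in swum NSG mice, and Muc1 (4.22), at 16.2 and 0.816 FPKM in these groups. The negative difference of Papss2 was -2.99, of Slc25a1 -3.01 and of Abat -3.27, the smallest of the negative called genes. The largest negative differences were those of Cyp4a10 (-14.79), Xist (-11.74), Cyp4a32 (-10.76), Igfbp1 (-9.77) and Cyp2b9 (-9.77). Sizes this large rest on a group value near 0, as with Cyp4a10 at 0.0120 FPKM in swum FKRPP448L-NSG mice.

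Liver transcripts rose with swimming in NSG mice and fell with it in FKRPP448L-NSG mice. A swimming effect common to both genotypes was argued against by the liver list's median of -2.57 in FKRPP448L-NSG against 2.26 in NSG mice. Scaling by a common factor would move all genes alike. The liver list stood apart from the median of all expressed genes, which moved by at most 0.0508 on the log2 scale in the 4 comparisons. The authors' scaling may itself hold that median in place, so shifts that depend on the expression level were not tested. RNA of liver tissue, which touches the diaphragm, is a candidate source, with Ttr at 3152 FPKM in swum NSG mice. The medians of the fixed liver list and of 35 further liver genes lay within 0.0993 (log2) of each other in each of the 4 comparisons. A varying amount of attached liver would give this, but so would any cause that moves liver genes together. The further genes were also chosen after the pattern was seen, so this value does not decide between sources. Amount alone does not account for all liver genes, since Apoa4 (3.20), Bhmt (2.73) and the fasting liver list (median 1.37) were higher in FKRPP448L-NSG mice that did not swim, where the liver list stood at 0.00. A change of liver-type expression within the diaphragm was not tested, and with 1 value per group it could not be seen whether a single mouse carried the signal.

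Glucocorticoid-responsive genes such as Ddit4, Mt2 and Per1 were higher in FKRPP448L-NSG mice that did not swim than in NSG mice that did not swim or swum FKRPP448L-NSG mice. More liver RNA in that group was argued against by the liver list's median of 0.00342 on the log2 scale between the groups that did not swim. Xist stood at 6.01 FPKM in that group, so a female mouse in it may have contributed, but whether the same mouse carried both signals cannot be told apart with 1 pooled value. Stress or fasting before tissue collection, in muscle or in attached liver, and an effect of the genotype were not tested and stay open. So does a difference between the sets of animals, whose mouse numbers form separate ranges.

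Macrophage genes called as higher after swimming in both genotypes were Itgam of the fixed macrophage list and, outside it, Alox15 and Timd4. The median log2 of the macrophage list was 0.47 in FKRPP448L-NSG and 0.82 in NSG mice. Both medians stood at percentile 100 of random lists, while calls in the list were not enriched after adjustment. Kupffer cells, the macrophages of the liver, were argued against as the common source by the liver list's median of -2.57 with swimming in FKRPP448L-NSG mice. The 5 Kupffer cell genes themselves had a median of 0.21 there, from -1.66 for Clec4f to 0.94 for Marco, and 0 were called by Cuffdiff (1 at an unadjusted p under 0.05) in the authors' deposited table. Peritoneal macrophages on the diaphragm surface had 5 of 6 marker genes with a higher value after swimming in FKRPP448L-NSG and 6 of 6 in NSG mice. With 0 of them called by Cuffdiff in FKRPP448L-NSG (1 at an unadjusted p under 0.05) and 1 in NSG mice in the authors' deposited table, they cannot be told apart from macrophages within the muscle, whose infiltration was not tested.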

How the results depend on the processing

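The alternatives without the genes that follow the liver list and with the variance divided by 3 were chosen after seeing the data, and all others before. The 4 counts of called genes stayed within 1.5 times when adjusted within a comparison (572, 1798, 344 and 1014 for genotype without swimming, genotype with swimming, swimming in FKRPP448L-NSG and swimming in NSG mice), limited to 1 FPKM, to an absolute log2 fold change of 1 or to genes with a called transcript. At a q of 0.01 the genotype count without swimming was 362, the swimming counts were 275 in FKRPP448L-NSG and 679 in NSG mice, and 97 genes differed in their swimming effect, as a stricter threshold must lower a count. Intervals that do not overlap were met by 99 genes without swimming (49.5% higher; 74 of them called as deposited), 626 with swimming, 18 for swimming in FKRPP448L-NSG (27.8% higher; 9 called as deposited) and 87 for swimming in NSG mice (59.8% higher); the cause was not tested. Without the genes that follow the liver list, 795 genes were called between swum genotypes (38.5% higher), 172 with swimming in FKRPP448L-NSG (25.6% higher) and 437 in NSG mice (76.0% higher), 53 differed in their swimming effect and the share of genes with the same sign of the swimming difference was 44.7%, since that set moved in opposite directions. Among the 53 were liver genes of another pattern, such as Aldob, Bhmt, Mat1a and Tat. The genotype count without swimming stayed at 669. With the variance divided by 3, 1016 genes differed in their swimming effect (966 with a lower effect in FKRPP448L-NSG mice), because the same differences then have a larger z. Other settings of that test gave 266 to 398. The share of called genes near Fkrp was 8.05% within 10 Mb (p = 0.0913, Fisher's exact test) and 6.30% over chromosome 7 (p = 0.0639), past no threshold before adjustment, and at a q of 0.01 within 20 Mb it was 4.57% (p = 0.0407); the cause was not tested. The genotype difference had the same sign in both states for 86.6% of genes after centring. Of the log2 fold changes of named genes, 200 kept sign and call in the most abundant transcript and 25 lost the call, and a pseudocount of 1 FPKM moved 69; no called value changed sign under these alternatives. Of the list medians 11 moved with the pseudocount, 4 with all members above 0 and 1 with centring, and 105, 112 and 115 did not. No paired analysis was possible because the tables hold 1 value per group, and for the same reason leaving out each mouse and a block by replicate number were not run. The depth of the libraries was unknown, so a lack of calls in a list says only that no difference was detectable.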

Other observations

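The lists of genes described here and the tests made on them were chosen after the data were seen. Genes of MHC class II, which present antigen on macrophages, dendritic cells and B cells, were higher in FKRPP448L-NSG mice in both states. In the same comparisons 16 and 9 of 25 macrophage genes were higher without and with swimming. So were 6 and 8 of 12 lung genes, with 1 lung gene lower with swimming. Which tissue carried the MHC class II genes was not tested. H2-Ab1 was at 72.9 FPKM (25.4 to 120.5) against 14.1 FPKM (5.44 to 22.9) without swimming (log2 2.37) and was higher by 2.52 with swimming, and Cd74 by 1.90 and 2.41. Of 7 genes 6 were higher without and 6 with swimming in the authors' deposited table (6 and 7 adjusted over the list alone; medians 2.03 and 2.44), while swimming itself left 0 called by Cuffdiff in either genotype (0 at an unadjusted p under 0.05; 0 adjusted over the list alone). Imprinted genes, many of them active in growing fetal tissue, were higher as well. Peg10 was at 2.41 against 0.206 FPKM without swimming (log2 3.55) and higher by 2.62 with it. Igf2, Mest, Peg3, Zdbf2 and Zim1 were higher in both states, with log2 fold changes of 2.56, 2.29, 2.38, 1.66 and 1.84 without swimming. Of 18 imprinted genes 7 were higher in each state in the authors' deposited table (11 and 9 adjusted over the list alone; medians 1.01 and 1.19), and Dlk1 (-0.02) was not called.

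Genes that the liver switches on in fasting differed between the groups that did not swim, where the liver list had a median of 0.00, and went with the liver list in the comparisons of swum NSG mice. Igfbp1 was at 83.2 FPKM (0 to 175) in FKRPP448L-NSG against 3.77 FPKM (0.0296 to 7.51) in NSG mice that did not swim (log2 4.46), and the fatty acid hydroxylase Cyp4a10 was higher by 5.04. Of 10 such genes 3 were higher there in the authors' deposited table (5 adjusted over the list alone; median log2 1.37), 7 were lower in swum FKRPP448L-NSG than in swum NSG mice (8 adjusted over the list alone; median -4.57), 6 fell with swimming in FKRPP448L-NSG (9 adjusted over the list alone; median -4.41) and 6 rose with it in NSG mice (9 adjusted over the list alone; median 1.86). A set of 35 further liver genes had 0 called by Cuffdiff between the groups that did not swim in the authors' deposited table (2 at an unadjusted p under 0.05; 0 adjusted over the list alone), 34 lower in swum FKRPP448L-NSG mice, 31 that fell with swimming in FKRPP448L-NSG and 29 that rose with it in NSG mice (34, 34 and 34 adjusted over the list alone).

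Genes of other organs and cell types gave these values. In the lung list 6 of 12 genes were higher in FKRPP448L-NSG mice without and 8 with swimming in the authors' deposited table (8 and 11 adjusted over the list alone), and 1, Abca3, was lower with swimming (-1.62). Sftpd (-1.93) and Scgb1a1 (-3.31) fell with swimming in FKRPP448L-NSG mice. The genotype differences of Slc34a2 without and with swimming were 5.13 and 2.21. In the simple epithelium list 7 of 10 genes were lower in FKRPP448L-NSG than in NSG mice that did not swim and 6 fell with swimming in NSG mice in the authors' deposited table (7 and 8 adjusted over the list alone), with Ehf at -4.45 and -5.44. Of 5 Kupffer cell genes 2, Clec4f (2.38) and Vsig4 (1.83), rose with swimming in NSG mice, and both were lower in swum FKRPP448L-NSG than in swum NSG mice (-4.18 and -2.24) in the authors' deposited table (2 and 2 adjusted over the list alone). Of 6 peritoneal macrophage genes 1, Garnl3, rose with swimming in NSG mice (1.84) and 1, Gata6, was lower in swum FKRPP448L-NSG than in swum NSG mice (-1.40) in the authors' deposited table (1 and 1 adjusted over the list alone).

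Targets of p53 were examined because Cdkn1a and Eda2r were higher in both states, and most of the list was not called. Phlda3 was higher by 1.13 without and 1.91 with swimming, whereas Mdm2 (0.17 and 0.29), Ccng1 (-0.48 and -0.08) and Bax (-0.15 and 0.09) were not called. Of 16 genes 4 were higher without swimming, and with swimming 3 were higher and 1 was lower in the authors' deposited table (4 and 5 adjusted over the list alone; medians 0.18 and 0.00).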
